A study of Mus musculus with 9 samples.

How the data were processed

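Small RNA was sequenced from 9 libraries of primary peritubular myoid cells, the contractile cells that surround the seminiferous tubules of the testis, from C57BL/6J mice. Per the labels, cells were grown in DMEM/F12 with 10% serum at 37 °C and 5% CO2, total RNA was extracted with TRNzol, and libraries were made by the standard protocols of the sequencing company. The groups were untreated cells (NC) and cells collected 1 h (H1) or 6 h (H6) after 30 min at 42 °C, with 3 libraries each. The labels number the libraries of a group 1 to 3 and do not say whether they came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical. Whether the numbers pair the libraries was checked by correlating deviations from the group means. Between NC and H1 same-numbered libraries had correlations of 0.220, 0.102 and 0.258 for structural families, all over 0.1, the bound for taking numbers as pairs. For miRNAs they were 0.275, 0.0766 and 0.134, and for piRNAs 0.195, 0.314 and -0.0414, not all over 0.1. With H6 in the pair they ran from -0.265 to 0.0872 for miRNAs, from -0.335 to -0.0405 for piRNAs and from -0.499 to 0.0597 for structural families. The numbers thus met the bound between NC and H1 in structural families and in no other class or pair of groups, and the labels do not say what a number stands for. Differently numbered libraries ran from -0.327 (NC_2 and H6_1) to 0.625 (NC_3 and H6_1) in structural families, with 0.342 for NC_1 and H6_2 and 0.434 for NC_2 and H6_3. Meeting the bound therefore does not show that numbers mark pairs.

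The read count of each small RNA in each library is used as the authors deposited it. The submitters' processing notes name Bowtie2 and the genome build mm10 without a role or version. How reads were aligned, the counting rule and the adapter trimming are not given in the sources used here. The deposited table also holds an RPM value (reads scaled to a common library total) for each count. Per the file headers that value is named TPM, but it is the count divided by 1 number per library with no length term, and a count of 0 is written as 0.001. These RPM values were used only to recover that number, never in a test.

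A pair of further tables holds the authors' own comparisons for miRNAs and for piRNAs. Their log2 ratios are, per the file headers, ratios between groups, and the deposited p-values and q-values come from a test that the sources used here do not name. Those tables also give counts pooled over a group. In the column used for each group, 2111 of 2117 pooled miRNA counts equalled the sum of the 3 libraries exactly, and 6508 of 6508 pooled piRNA counts did. The 6 that differed belong to 5 miRNAs (miR-328-3p, miR-1981-3p, miR-712-5p, miR-665-3p and miR-326-5p). The table of libraries types 7 named miRNAs as hairpin, and all 3 of these that the authors' tables list are among the 5. For 275 entries of a comparison, the sums differed by a log2 ratio over 1.1 with over 200 reads, and the authors' tables leave out 7 of these, which belong to 5 miRNAs. Together 12 miRNAs have counts that are doubtful for one of these reasons. They stayed in the tests as deposited, and an alternative left them out. This check of counts was made after the values were seen.

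The table of libraries lists 9437 entries. Named miRNAs (1378) and predicted miRNAs (822) were tested together, as were named (2419) and predicted piRNAs (4066), and 595 Rfam families of structural RNA (rRNA, tRNA, snRNA, snoRNA and others) were tested apart. The 4 genomic entries (repeat, exon, intron, intergenic) name no RNA and stayed out of library sizes and tests. They hold 26.4% to 50.2% of the listed reads, 38.2% on average. The 153 Rfam families of miRNA precursors were not tested, because they count the same transcripts as the miRNAs. Listed reads per library ran from 16273687 to 23462448.

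Counts were tested with edgeR 4.0.16 in R 4.3.3. RNAs were kept by filterByExpr, libraries scaled by TMM, and a quasi-likelihood model was fitted to all 9 libraries, so that the 3 groups share an estimate of the spread. RNAs past an adjusted p of 0.05 (Benjamini-Hochberg, within a class and comparison) were called. This left 893 miRNAs (664 named, 229 predicted), 1576 piRNAs (97 named, 1479 predicted) and 166 structural families. Levels of single RNAs are TMM-scaled RPM over the reads of the class. Summed levels of lists are RPM over all miRNA reads without TMM scaling. All p-values are two-sided unless stated. Pearson correlations of fold changes between comparisons are across RNAs, which are not independent replicates.

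Before the data were examined, the groups, the tests, the rule for named RNAs, 22 lists of miRNAs and most alternatives were fixed. Lists were drawn from textbook knowledge, and 21 had at least 3 tested members. The list of endothelial miRNAs has 2 and is given as a level. Lists of protein-coding genes fixed with them could not be tested, because the tables hold small RNAs. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside an estimated correlation and with fry. The text names, per comparison, class and direction, the 10 largest changes among called RNAs whose 3 libraries all lie apart, or, where fewer than 5 were called, the 5 with the smallest p, and of predicted RNAs the 2 with the smallest p. It also names the 5 most abundant RNAs of a class and, from each list, the 2 most abundant members and the one with the smallest p.

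The scripts were tested on simulated counts with the real means and library sizes. In 5 simulations of H1 against NC, 13.1% of miRNAs changed 4-fold and 59.4% of those changed 16-fold were called. For H6 against NC the shares were 12.5% and 60.3%. Of piRNAs changed 16-fold, 5.46% were called for H1 against NC and 0% for H6 against NC. Of structural families changed 4-fold, 25.5% and 30.9% were called. With no change in the simulated counts, camera called 1 of 420 lists. With the miR-322 list shifted 2-fold in H1, camera called it in 16 of 20 simulations, and in 1 of 20 with an estimated correlation. Each RNA was drawn on its own, so list members were not correlated in these simulations. In the data the estimated correlation at 1 h was 0.341 for the miR-322 list and 0.365 for the germ cell list. The simulations therefore do not test the preset correlation of 0.01 where members move together.

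Counts of predicted RNAs are 0 or at least 10, so a fold against a group at 0 in all 3 libraries is given as a lower bound from a floor of 9 reads per library for predicted RNAs and 3 for named ones. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. The SE of a log2 fold change is its size divided by the square root of the edgeR F statistic. It includes the spread between libraries and is approximate, most of all where a group is at 0. Median 95% intervals were built from the median SE and a t quantile at the residual degrees of freedom. They leave out the degrees of freedom that edgeR adds by sharing information across RNAs. Positions of predicted RNAs are those of the deposited table on mm10, and their place in genes comes from GENCODE M21 for the same assembly. Near-identical miRNAs (the let-7, miR-465 and miR-7 families among them) and overlapping repeats can share reads, and their counts are uncertain to that extent. Alternatives were DESeq2 1.42.0, other scalings and filters, a replicate block, each library left out, other thresholds and, added after the data were seen, robust estimation, quality weights, other sets of RNAs, the loss of a pair of libraries that stood apart, for piRNAs at 6 h DESeq2 without each H6 library, the block with only NC and H1, and for the germ cell list an estimated correlation without NC_3. For each named RNA the library whose loss moved the log2 fold change furthest toward or past 0 was also found, and the value without it is given where a fold change in the text turned or shrank by over 1.5 times on the log2 scale.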

Results

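The small RNA of peritubular myoid cells, the smooth-muscle-like cells that wrap the seminiferous tubules, was sequenced before and after a short heat exposure. Cells kept at 37 °C (NC) were compared with cells collected 1 h (H1) and 6 h (H6) after 30 min at 42 °C, with 3 libraries in each of the 3 groups. The tables listed 16273687 to 23462448 reads per library, of which 6725287 to 16149690 were miRNA reads. Named miRNAs took 41.0% to 68.8% of the listed reads. Families of rRNA took 11.4% in NC_1, 7.83% in H6_2 and 5.27% in H6_3, against 0.843% to 3.77% in the other 6 libraries.

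**Figure D1:**
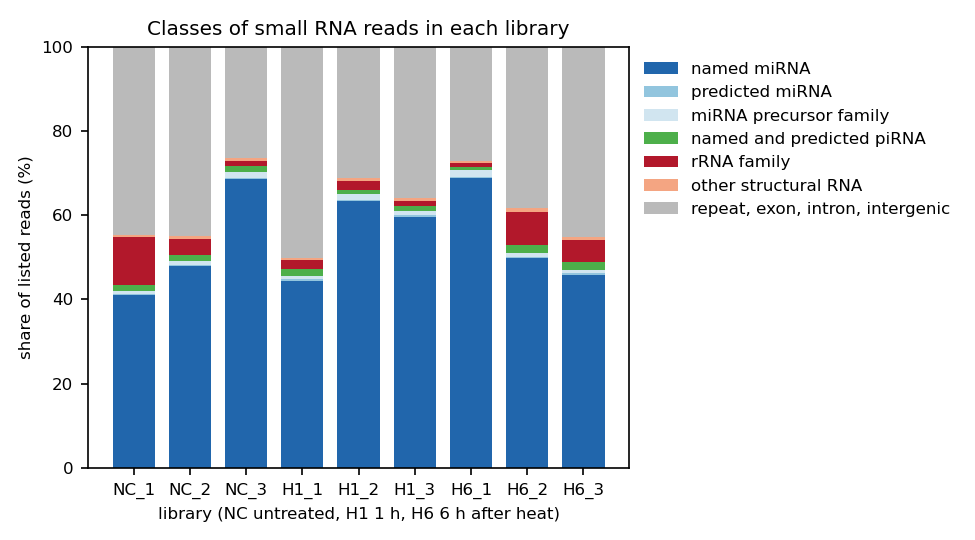
Share of listed reads (%, y axis) in each class of small RNA for the 9 libraries (x axis), stacked to 100%. Named miRNAs range from 41.0% to 68.8%, and rRNA families reach 11.4% in NC_1.

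The most abundant miRNAs of the cells were let-7 members. In NC, H1 and H6, let-7c-5p stood at 219885 ± 11788, 256175 ± 27645 and 196924 ± 12719 RPM (scaled to the miRNA reads of a library) (SD, n = 3), and let-7b-5p at 181018 ± 53631, 181571 ± 25895 and 180291 ± 29018. They were followed by miR-22-3p (55331 ± 28583 in NC), miR-652-3p (44152 ± 12703) and let-7a-5p (36337 ± 14162). The smooth muscle miRNA miR-143-3p was at 19259 ± 12657, 19292 ± 3516 and 19193 ± 4186, and miR-21a-5p, abundant in fibroblasts, at 22283 ± 11062, 23879 ± 2924 and 15833 ± 7051. In RPM without TMM scaling, the epithelial and Sertoli list summed to 1105 ± 231 in NC and the endothelial list to 725 ± 550. The germ cell list summed to 36497 in NC_3 alone, against 726 to 2179 in the other 8 libraries.

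Members of the fixed lists spanned a wide range of levels in untreated cells. Among families tied to growth and the cell cycle, miR-92a-3p stood at 9961 ± 5970 and miR-93-5p at 855 ± 164 RPM (SD, n = 3), miR-34a-5p at 12676 ± 9077 and miR-34b-3p at 528 ± 343, and miR-16-5p at 2425 ± 1053 and miR-15b-5p at 1876 ± 339. The smooth muscle miRNA miR-145a-5p stood at 1820 ± 698, and the collagen-repressing miR-29a-3p and miR-29b-1-5p at 4723 ± 1487 and 765 ± 165. The levels of miR-30d-5p and miR-30a-5p were 1039 ± 357 and 149 ± 130.0, and those of miR-24-3p and miR-23a-3p 8169 ± 2650 and 7190 ± 1122. The inflammation miRNAs miR-155-5p and miR-146b-5p were at 2792 ± 1065 and 195 ± 193, and miR-193a-5p and miR-365-2-5p of the hypoxia list at 496 ± 249.5 and 412 ± 271. In the imprinted Dlk1-Dio3 region miR-433-3p was at 1653 ± 436, and in the Sfmbt2 cluster miR-467d-5p and miR-467a-5p were at 194 ± 94.1 and 114 ± 84.4. Of miRNAs of other cell types, miR-183-5p (epithelial) was at 329 ± 175, miR-486a-5p (erythroid, not told apart from miR-486b-5p) at 109 ± 109, and the endothelial miR-126a-3p and miR-126a-5p at 723 ± 528 and 4.62 ± 2.14. The germ cell miRNA miR-465a-3p, not told apart from miR-465b-3p and miR-465c-3p, was at 4066 ± 6944 in NC, 56.1 ± 28.9 in H1 and 169 ± 72.0 in H6. Among RNA fragments listed as miRNA, miR-2137 was at 766 ± 496.

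The most abundant piRNA entries were the predicted novel_pir1889 (62698 ± 26992 in NC, 70399 ± 22086 in H1 and 46373 ± 50532 in H6, in RPM scaled to piRNA reads) and novel_pir2011 (48184 ± 31381 in NC, 79529 ± 53023 in H1 and 45966 ± 42826 in H6). Named ones were mmu_piR_017405 (53238 ± 28303 in NC, 48994 ± 42284 in H1 and 68151 ± 50990 in H6), mmu_piR_000691 (30037 ± 8542 in NC, 37612 ± 19000 in H1 and 49338 ± 25821 in H6) and mmu_piR_010700, which rested on NC_3. Among structural families the most abundant were RF01960, RF00002, RF00023, RF00177 and RF00005, of which RF01960 had 1439969, 347114 and 129646 reads in NC and RF00002 had 347563, 220103 and 129681. The libraries of H1 held 241357, 191841 and 132428 reads of RF01960, and those of H6 held 64033, 863911 and 701810.

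The comparison of H1 with NC addressed the small RNA response 1 h after heat. As a set, the X-linked cluster of miR-322, miR-503 and miR-351, whose members include relatives of the growth-restraining miR-15 and miR-16, was lower after heat. Its summed level was 2854 ± 494 RPM in NC and 1480 ± 415 in H1 (SD, n = 3). By camera the list fell (adjusted p = 0.00231), with 8 of its 9 tested members lower and a median log2 fold change of -0.92. With an estimated correlation the adjusted p was 0.807. The most abundant member, miR-351-5p, was at 1463 ± 275 in NC and 616 ± 102 in H1, a log2 fold change of -1.25 ± 0.32 (SE) with all 3 libraries apart. It was the only member past the threshold adjusted over the list alone (1), and 0 members passed over all miRNAs tested (edgeR adjusted p = 0.651 for miR-351-5p). The list's adjusted p was 0.143 without H1_2 and 0.165 without NC_3, and ran from 1.87e-05 to 0.807 over all alternatives.

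**Figure D2:**
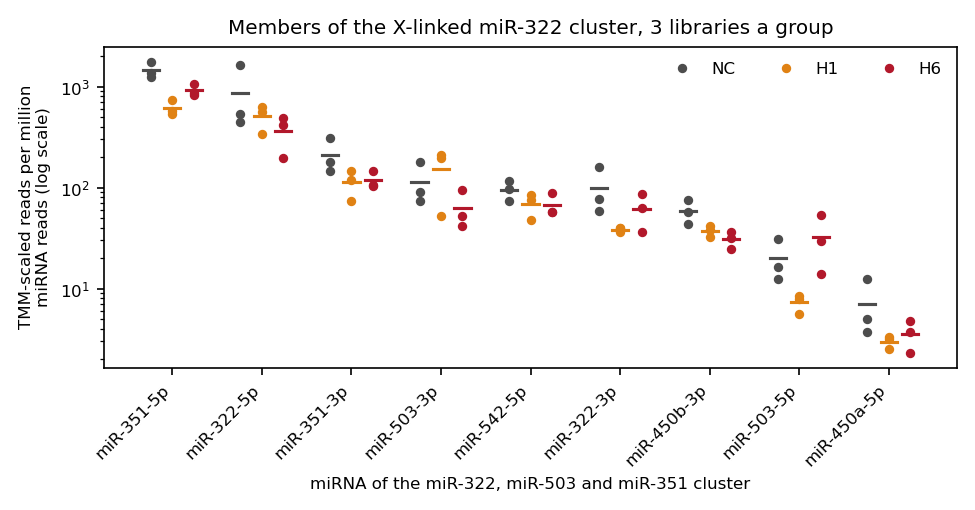
TMM-scaled RPM (y axis, log scale) of the 9 tested members of the miR-322, miR-503 and miR-351 cluster (x axis); points are libraries and short lines the mean of 3 libraries in NC, H1 and H6. For miR-351-5p the means are 1463, 616 and 920.

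The germ cell list and the list of the Sfmbt2 cluster, a rodent miRNA cluster in an intron of Sfmbt2, were also lower by camera at 1 h. The germ cell list fell (adjusted p = 0.00440), with 22 of 29 members lower, a median log2 fold change of -3.62, 13 members past the threshold adjusted over the list alone and 0 over all miRNAs. With an estimated correlation the adjusted p was 0.807. Of its members, 11 stood over 4 times above every other library in NC_3, where miR-470-5p reached 18091 RPM against 463 or less elsewhere, and without NC_3 the list's direction turned to higher (adjusted p = 0.385, and 0.860 with an estimated correlation). Without H1_1 its adjusted p was 0.0544, and over all alternatives it ran from 6.13e-14 to 0.860. The Sfmbt2 list fell (adjusted p = 0.0183), with 32 of 38 members lower, a median of -0.47 and 0 members past the threshold adjusted over the list alone or over all miRNAs. With an estimated correlation the adjusted p was 0.807, and without NC_3, H1_3 or H1_1 the list's adjusted p was 0.782, 0.266 or 0.0544. With all named small RNAs in 1 fit it was 0.146, and over all alternatives it ran from 0.00378 to 0.807. With the replicate block and only the libraries of NC and H1 in the fit, the adjusted p of the miR-322, germ cell and Sfmbt2 lists was 0.0139, 0.317 and 0.0673. By fry, which tests whether members move one way without comparing them with other miRNAs, 0 lists passed in each comparison. For the miR-322 list its adjusted p was 0.422 at 1 h and 0.542 at 6 h, and for the germ cell and Sfmbt2 lists 0.770 at 1 h.

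Among single miRNAs, edgeR called 0 of 893 at 1 h (smallest adjusted p = 0.136), where 61 had an unadjusted p under 0.05 (18 higher, 43 lower; chance gives 44.6) and DESeq2 called 4. Of the named miRNAs with the smallest p toward higher levels, one belongs to the imprinted Dlk1-Dio3 region and one to the p53-regulated miR-34 family. The level of miR-134-5p was 332 ± 61.6 in NC and 813 ± 339 in H1 (log2 1.29 ± 0.42, SE), with all 3 heated libraries above the controls. For miR-34c-3p the levels were 262 ± 144 and 816 ± 394 (1.64 ± 0.57). Higher in all 3 heated libraries were also miR-342-5p (38.7 ± 6.13 and 86.2 ± 38.0), miR-1198-5p (709.7 ± 203 and 1781 ± 803) and miR-5114 (17.7 ± 1.99 and 61.03 ± 38.9), with a log2 fold change of 1.79 that was 1.16 without H1_3. On the lower side, let-7b-3p was at 59.8 ± 23.4 and 16.7 ± 10.3 (log2 -1.84 ± 0.52). The stem cell miRNAs miR-302c-3p and miR-302b-3p had log2 fold changes of -4.42 ± 1.23 and -3.62 ± 1.01 at levels of 11.8 ± 11.3 and 9.16 ± 8.47 in NC. The Sfmbt2 member miR-669f-3p had -2.10 ± 0.64. None of these passed the edgeR test (adjusted p from 0.651 to 0.695). For 82 of the 893 miRNAs (9.18%) the 3 libraries of H1 and NC did not overlap, and the median 95% interval spanned a factor of 3.39 in each direction. Chance gives 10% without ties, and less for RNAs with libraries tied at 0, because ties count as overlap.

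Some predicted miRNAs inside exons separated groups completely in the listed reads, where counts of predicted RNAs are 0 or at least 10. The predicted miRNA novel_mir81, at chr12:44210021-44210065 on the minus strand in the untranslated part of an exon of Dnajb9 (an endoplasmic reticulum chaperone gene), had 92, 16 and 65 reads in H1 and 0 in all NC and H6 libraries, at least 5.91-fold higher than NC (3.67-fold without H1_1). The opposite held for novel_mir889 at chr4:132884366-132884421 in an untranslated exon part of Stx12. It was at 3.67 ± 1.02 RPM in NC and 0 in all H1 libraries, at least 4.37-fold lower (edgeR adjusted p = 0.136). For novel_mir81 the separation of H1 from NC rests on the listing of reads. Its 16 reads in H1_2 were 1.19 RPM, from 13952633 miRNA reads, while NC_1 had only 6725287. A level in NC_1 near that of H1_2 could thus be listed at 0, so complete separation from NC was not shown. DESeq2 called novel_mir81, novel_mir889, miR-351-5p and miR-302c-3p, with adjusted p of 0.0233, 0.000108, 0.0294 and 0.0401. The predicted miRNA novel_mir8, at chr12:109654628-109654693 in an exon of the imprinted long RNA Rian, was at 0.764 ± 0.736 and 8.43 ± 4.85 (log2 3.47 ± 1.12). For novel_mir649, at chr16:5255758-5255839 in an intron of Eef2kmt, the H1 libraries were all at 0, at least 2.31-fold lower.

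**Figure D3:**
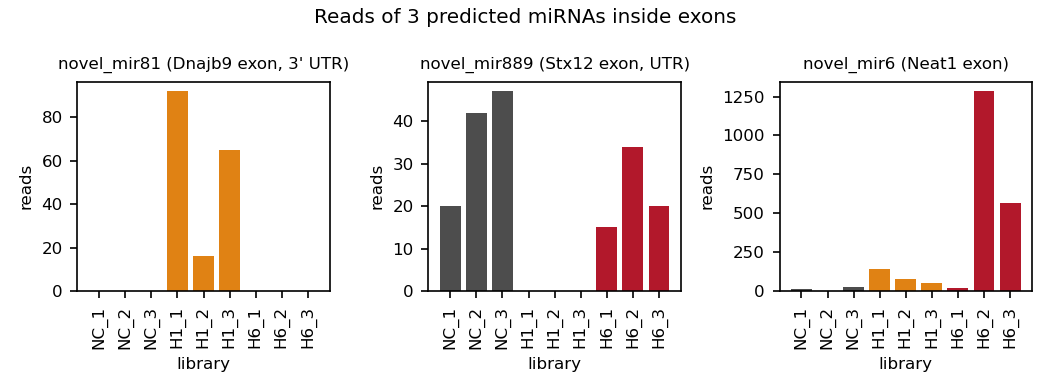
Reads (y axis) of novel_mir81 (Dnajb9 exon), novel_mir889 (Stx12 exon) and novel_mir6 (Neat1 exon) in the 9 libraries (x axis); each bar is a library. The predicted miRNA in Dnajb9 has 92, 16 and 65 reads in H1 and 0 elsewhere.

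The other lists did not pass at 1 h, and none had a member past the threshold adjusted over the list alone. Directions, adjusted p by camera and member examples were as follows. The Dlk1-Dio3 list was higher in 44 of 78 members (adjusted p = 0.253), with miR-127-3p at 12462 ± 2398 in NC and 15472 ± 3234 in H1. The list of rRNA, tRNA and snoRNA fragments listed as miRNA had the same adjusted p of 0.253 toward higher levels. At 0.336 stood the miR-17-92 list and the epithelial and Sertoli list and the blood list (lower) and the miR-34, mesenchymal, immediate-early and inflammation lists (higher). Lists toward lower levels were miR-30 (0.360), serum and liver (0.372), hypoxia (0.428), miR-15 and miR-16 (0.583), let-7 (0.701) and miRNAs reported in heat shock (0.906). Toward higher levels were miR-23, miR-27 and miR-24 (0.468) and smooth muscle (0.825). For miR-29 the test pointed higher (0.741) at a median of -0.01. The erythroid miR-451a had 77.7 ± 52.9 in NC and 9.46 ± 3.54 in H1, a log2 fold change of -3.04 ± 1.15 (adjusted p = 0.689), and miR-212-5p had 38.7 ± 12.1 and 84.2 ± 21.3. For the miR-15 and miR-16 list the test pointed lower at a median of 0.03. Members with the smallest p in their list had log2 fold changes of -1.15 ± 0.52 (miR-106b-5p), -1.37 ± 0.50 (miR-322-3p), -0.40 ± 0.71 (miR-145a-3p), -1.86 ± 0.76 (miR-196a-1-3p), -0.44 ± 0.38 (miR-29a-3p), -0.82 ± 0.54 (miR-30a-3p), 1.00 ± 0.61 (miR-23b-5p), 1.80 ± 0.91 (miR-223-3p), -1.88 ± 0.88 (miR-26a-2-3p), 2.12 ± 0.97 (miR-690) and -0.94 ± 1.38 (miR-126a-5p, SE throughout). Many moved with 1 library. Without NC_3 the values of miR-145a-3p, miR-29a-3p and miR-30a-3p were 0.73, -0.13 and -0.05, and those of miR-106b-5p, miR-322-3p and miR-196a-1-3p -0.76, -0.76 and -1.18. That of miR-223-3p was 1.19 without H1_3, that of miR-690 was 0.79 without H1_2 and that of miR-126a-5p -0.35 without NC_1.

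For piRNAs, edgeR called 0 of 1576 at 1 h (smallest adjusted p = 0.668), where 69 had an unadjusted p under 0.05 (48 higher, 21 lower; chance gives 78.8) and DESeq2 called 7. Higher in all 3 heated libraries were mmu_piR_000616 (316 ± 19.1 RPM in NC, 1163 ± 901 in H1), mmu_piR_037320 (254 ± 16.6 and 629 ± 279) and mmu_piR_018376 (55.8 ± 42.0 and 214 ± 149). The predicted piRNAs novel_pir2037 and novel_pir2039, in an ERVL long terminal repeat at chr12:81001490-81001617 in intergenic sequence, were at 0 in all NC libraries and at least 1.97-fold and 1.82-fold higher in H1. Lower in H1 was novel_pir2482, in a LINE-1 repeat at chr15:57432781-57433818, at 91.3 ± 10.3 in NC and 0 in H1, at least 2.52-fold lower. Several named piRNAs were high in NC_3 alone. There mmu_piR_010700 had 81817 reads against 49 and 126 in the other NC libraries, and mmu_piR_016536 had 778 against 2 and 1 and 0 in H1. Libraries did not overlap for 96 piRNAs (6.09%), and the median interval spanned a factor of 30.4. Chance is under 10% here and was not computed, since 1479 of the 1576 piRNAs are predicted ones, many tied at 0. Log2 fold changes were 1.32 ± 0.84 for mmu_piR_028055, 1.28 ± 0.95 for mmu_piR_019200, -7.65 ± 2.44 for mmu_piR_032867, -8.11 ± 2.69 for mmu_piR_030789 and -6.29 ± 2.33 for mmu_piR_012524. The last 3 rested on NC_3, with 4, 4 and 962, 0, 3 and 618, and 9, 1 and 273 reads in NC, and without NC_3 they were -0.69, -0.51 and -1.56. Without NC_3 mmu_piR_010700 turned from -7.28 to 1.69, and without H1_3 mmu_piR_019200 was at 0.23. The log2 fold changes of mmu_piR_000616, mmu_piR_037320 and mmu_piR_018376, 1.88, 1.3 and 1.92, were 1.03, 0.86 and 1.19 without H1_3. The LINE-1 piRNA novel_pir2985 at chr19:22852132-22852295, in an intron of Trpm3, was at 0 in all H1 libraries and in NC_3, at least 5.44-fold lower (2.91-fold without NC_2).

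For structural RNA, edgeR called 0 of 166 families at 1 h (smallest adjusted p = 0.624). An unadjusted p under 0.05 was found for 10 (6 higher, 4 lower; chance gives 8.3), and DESeq2 called 0. The spliceosomal U1 family (RF00003) had 278, 436 and 327 reads in NC and 427, 1303 and 1133 in H1, with a log2 fold change of 1.86 ± 0.62. The snoRNA family SNORD94 (RF00613) had 70, 62 and 42 against 136, 92 and 182 (1.86 ± 0.57), and SNORA38 (RF00428) had 23, 108 and 16 against 9, 12 and 7 (-1.77 ± 0.63). The tRNA family (RF00005) had 75254 reads in H1_3 and 2720 to 7399 in the other 8 libraries, and its log2 fold change was -0.04 without H1_3. Libraries did not overlap for 13 families (7.83%, chance 10%), and the median interval spanned a factor of 3.09. Log2 fold changes of the other families with the smallest p were 1.78 ± 0.59 (RF00412), 1.44 ± 0.57 (RF00405), -2.25 ± 0.90 (RF01294), -3.02 ± 1.22 (RF01184), -1.58 ± 0.72 (RF00584) and -1.87 ± 0.89 (RF00271). Without NC_1 those of RF01294, RF01184 and RF00584 were -0.33, -0.47 and -0.34 and that of RF00271 -0.96, and without NC_2 that of RF00428 was -0.79.

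The comparison of H6 with NC addressed the state of the cells 6 h after heat. The miR-322, miR-503 and miR-351 cluster was lower here too, at 1805 ± 425 RPM in H6 against 2854 ± 494 in NC (SD, n = 3). By camera the list fell (adjusted p = 0.0150), with 8 of 9 members lower and a median log2 fold change of -0.85. With an estimated correlation the adjusted p was 0.845, and 0 members passed the threshold adjusted over the list alone or over all miRNAs. Its member miR-450b-3p was at 58.9 ± 16.5 in NC and 30.8 ± 5.71 in H6 (log2 -0.93 ± 0.38, and -0.61 without NC_3), and miR-322-5p at 873 ± 658 and 366 ± 152 (-1.26 ± 0.59, and -0.33 without NC_3). The list's adjusted p was 0.424 without NC_3, 0.147 without H6_2, 0.0521 without H6_1 and 0.0831 with all named small RNAs in 1 fit, and ran from 0.00140 to 0.845 over all alternatives. The germ cell list, whose summed level was highest in NC_3, had 22 of 29 members lower (adjusted p = 0.0850, and 0.845 with an estimated correlation). Without NC_3 its direction turned to higher (adjusted p = 0.000531, and 0.879 with an estimated correlation). The list was lower without NC_2 (adjusted p = 2.33e-08), NC_1 (2.01e-05) or H6_2 (0.0226).

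Among single miRNAs, edgeR called 0 of 893 at 6 h (smallest adjusted p = 0.948), where 43 had an unadjusted p under 0.05 (17 higher, 26 lower; chance gives 44.6) and DESeq2 called 4. Among the smallest p toward higher levels were the pancreas-type miR-216a-5p and miR-217-5p, both low and neither past the test. For miR-216a-5p the levels were 0.944 ± 0.729 in NC and 8.27 ± 5.71 in H6 (log2 3.08 ± 0.92, SE), and H6_3 (2.12 RPM) was just above the highest NC library (1.78). For miR-217-5p they were 0.244 ± 0.328 and 2.44 ± 1.54, with 0.706 in H6_3 against at most 0.617 in NC, and its H1 libraries (1.01, 1.85 and 2.34) were above NC too. The level of miR-5126 was 208 ± 41.8 in NC, 409 ± 72.6 in H1 and 493 ± 261 in H6, and that of miR-709 was 2.03 ± 1.15, 3.63 ± 3.78 and 40.8 ± 43.8. The H6 level of miR-709 rested on H6_2 (87.4) and H6_3 (34.6), while H6_1 (0.451) was the lowest of the 9 libraries. The muscle miRNA miR-1a-3p had a log2 fold change of 7.05 ± 2.33 that came from H6_3, where it stood at 237 RPM against 1.41 or less elsewhere, and the log2 fold change was 0.82 without H6_3. On the lower side, miR-5099 was at 1431 ± 957 in NC and 427 ± 108 in H6 (log2 -1.74 ± 0.55, and -0.96 without NC_2). High in NC_3 were miR-203-3p (-3.89 ± 1.16), miR-204-5p (-4.34 ± 1.55) and miR-471-3p (-5.87 ± 2.17), which without NC_3 were at -1.02, -0.02 and 2.11. For 48 miRNAs (5.38%, chance at most 10%) libraries did not overlap, and the median interval spanned a factor of 3.38.

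The counts of miR-328-3p do not support a direction at 6 h. In the table of libraries it had 2, 7 and 2 reads in H6 against 49413, 3 and 10 in NC, a log2 fold change of -12.81 ± 4.35 (edgeR adjusted p = 0.948) that DESeq2 called (adjusted p = 0.000764). Without NC_1 the log2 fold change was -0.56. In the authors' deposited table, however, the H6 group holds 289550 reads of miR-328-3p, where the libraries sum to 11, and its log2 ratio of H6 to H1 is 1.06. With this and the other doubtful miRNAs left out, DESeq2 called 3 miRNAs at 6 h and edgeR 0.

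Predicted miRNAs with the smallest p at 6 h included novel_mir6, at chr19:5840780-5840838 in an exon of the nuclear long RNA Neat1. It had 10, 0 and 23 reads in NC, 139, 77 and 54 in H1 and 22, 1283 and 565 in H6, with a log2 fold change of 5.87 ± 1.64 (edgeR adjusted p = 0.948, DESeq2 0.00449). For novel_mir4, in intergenic sequence at chr1:155262708-155262755, it was 4.30 ± 1.28 (DESeq2 adjusted p = 0.0261). Both rested on H6_2 and H6_3, and novel_mir4 was at 3.03, 121 and 35.7 RPM in H6 against 4.11, 3.22 and 0.823 in NC. At 0 in all H6 libraries were novel_mir71 at chr14:78732925-78732996, at least 1.70-fold lower than NC but with no bound above 1 without NC_2, and novel_mir586 at chr8:75033668-75033729 in an untranslated exon part of Tom1, at least 2.09-fold lower.

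The other 19 lists did not pass at 6 h and had 0 members past the threshold adjusted over the list alone, as had the germ cell list. Toward lower levels stood let-7 (adjusted p = 0.0777, 17 of 20 members lower), Sfmbt2 (0.129), epithelial and Sertoli (0.139), serum and liver (0.139), immediate-early (0.187), miR-15 and miR-16 (0.244) and blood (0.341). The Sertoli miRNA miR-202-3p was at 519 ± 263, 382 ± 188 and 228 ± 53.8 in NC, H1 and H6. Lists of miR-17-92 and miR-34 (lower) and of smooth muscle and RNA fragments (higher) had an adjusted p of 0.450. Further toward lower levels were miR-30 (0.508), miRNAs reported in heat shock (0.587), hypoxia (0.601), the miR-23, miR-27 and miR-24 clusters (0.656), mesenchymal and inflammation (both 0.717). Dlk1-Dio3 (0.656, 38 of 78 members higher, median -0.03) and miR-29 (0.717, median -0.04) pointed higher by the test and lower by the median. The Dlk1-Dio3 member miR-329-5p was at 8.23 ± 0.651 in NC, 13.4 ± 2.63 in H1 and 14.1 ± 0.373 in H6. The list reported in heat shock had a median of -0.16 and a mean of 0.22, the mean drawn up by miR-1a-3p. Members with the smallest p in their list had log2 fold changes of -1.31 ± 0.72 (miR-25-5p), -1.19 ± 0.61 (let-7f-2-3p), -0.56 ± 0.36 (miR-449a-5p), 1.36 ± 0.80 (miR-199b-5p), 0.67 ± 0.42 (miR-29b-2-5p), -0.88 ± 0.45 (miR-30c-2-3p), 0.79 ± 0.55 (miR-24-3p), -0.73 ± 0.48 (miR-132-5p), 1.69 ± 0.91 (miR-223-3p), -0.66 ± 0.58 (miR-365-2-5p), -5.13 ± 2.22 (miR-467h), -1.82 ± 0.72 (miR-486b-3p) and 1.96 ± 1.40 (miR-126a-5p, SE throughout). The last rested on H6_3, with 51.1 RPM against 7.05 or less elsewhere, and was -1.56 without it. Without NC_1 miR-365-2-5p was at 0.03, without H6_2 miR-24-3p was at 0.00, miR-132-5p at -0.28 and miR-30c-2-3p at -0.50, and without H6_1 miR-223-3p was at 0.30 and miR-199b-5p at 0.88. Without NC_2 miR-25-5p was at -0.74 and let-7f-2-3p at -0.70.

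For piRNAs, edgeR called 0 of 1576 at 6 h (smallest adjusted p = 0.187), where 159 had an unadjusted p under 0.05 (147 higher, 12 lower; chance gives 78.8) and DESeq2 called 79, all higher. In simulations without any change 6.27% of piRNAs had such a p, and a split that mixes H6 and NC libraries gave 260. The 159 and the 79 moved with H6_2. On the same 1576 piRNAs without it DESeq2 called 0 and edgeR gave 60 at an unadjusted p under 0.05, against 40 and 133 without H6_3 and 111 and 192 without H6_1. With the filter applied anew they were 0 and 81 of 1900 without H6_2, 49 and 141 of 1755 without H6_3 and 143 and 283 of 2125 without H6_1. In H6_2 and H6_3, 38 piRNAs stood over 4 times above every other library, of which 34 were among the 147 and 23 among the 79. Levels of piRNAs in H6_1 correlated better with NC_3 (r = 0.797, across piRNAs) than with its own group (mean r = 0.486). The ERVL-derived novel_pir2037 and novel_pir2039 at chr12:81001490-81001617 were at least 18.3-fold and 11.6-fold higher than in NC, where all 3 libraries were at 0 (DESeq2 adjusted p = 2.06e-06 and 6.75e-06). Their reads in H6 were 14, 470 and 132 and 17, 282 and 83, and without H6_2 the bounds were 6.15-fold and 4.54-fold. The named piRNA mmu_piR_000802 had 12929 and 3653 reads in H6_2 and H6_3 and 20 to 815 in the other 7 libraries (log2 5.56 ± 1.55, edgeR adjusted p = 0.328). Higher in all 3 H6 libraries were mmu_piR_028055 (96.1 ± 40.3 RPM in NC, 350 ± 260 in H6) and mmu_piR_000442 (89.8 ± 26.4 and 256 ± 116). At 0 in all H6 libraries were the LINE-1 piRNAs novel_pir1377 at chr10:114836245-114836735, and novel_pir4005 at chr9:92311620-92311835. The bounds of 1.18-fold and 6.84-fold lower than NC rested on NC_2, without which neither was above 1, and novel_pir4005 had 19, 210 and 0 reads in NC. Libraries did not overlap for 114 piRNAs (7.23%, chance under 10% with ties at 0), and the median interval spanned a factor of 30.7. Log2 fold changes were 1.02 ± 0.69 for mmu_piR_038428, 1.00 ± 0.69 for mmu_piR_037320, -3.53 ± 1.5 for mmu_piR_032015, -4.18 ± 1.96 for mmu_piR_015997, -4.53 ± 2.08 for mmu_piR_032867, -4.52 ± 2.22 for mmu_piR_030789 and -5.43 ± 2.43 for mmu_piR_010700. The last 5 rested on NC_3. Without it mmu_piR_032015 was at -1.40 and the other 4 turned to higher, at 1.20, 2.31, 3.09 and 3.43. The log2 fold change of mmu_piR_028055 (1.86) was 1.16 without H6_2, and that of mmu_piR_038428 was 0.57 without H6_3.

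For structural RNA, edgeR called 0 of 166 families at 6 h (smallest adjusted p = 0.991), where 1 had an unadjusted p under 0.05 (chance gives 8.3) and DESeq2 called 0. The spliceosomal U6 family (RF00026) had 1100, 2248 and 696 reads in NC and 1014, 7631 and 4167 in H6 (log2 1.38 ± 0.64). RNase P (RF00009) had 426, 852 and 207 against 250, 2126 and 1510, and 7SK (RF00100) had 807, 7580 and 780 against 330, 1768 and 1074. Libraries did not overlap for 5 families (3.01%, chance 10%), and the median interval spanned a factor of 3.06. Log2 fold changes of the other families with the smallest p were 0.96 ± 0.56 (RF00613), 0.80 ± 0.50 (RF00324), 1.1 ± 0.70 (RF02278), -3.52 ± 1.53 (RF01506), -1.67 ± 0.88 (RF01294), -1.82 ± 1.00 (RF00001) and -1.48 ± 0.85 (RF00594). Directions turned for RF02278 without H6_3 (-0.23), RF01294 without NC_1 (0.31) and RF00001 without NC_2 (0.62). Without NC_2 the values of RF01506, RF00100 and RF00594 were -1.54, -0.08 and -0.38, and without H6_2 those of RF00613, RF00026 and RF00324 were 0.47, 0.89 and 0.49.

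The comparison of H6 with H1 addressed the difference between both times after heat. Of 893 miRNAs edgeR called 0 (smallest adjusted p = 0.240), where 53 had an unadjusted p under 0.05 (27 higher, 26 lower; chance gives 44.6) and DESeq2 called 3. The guide strand miR-503-5p was at 7.29 ± 1.47 in H1 and 32.4 ± 20.1 in H6 (log2 2.15 ± 0.59, SE), beside 19.99 ± 9.84 in NC, and passed the threshold adjusted over the list alone (1 of 9 members). Also higher in all 3 H6 libraries were let-7b-3p (1.68 ± 0.52), miR-669a-3p (1.92 ± 0.58, not told apart from miR-669o-3p) and miR-671-5p (77.7 ± 16.2 in H1, 316 ± 186 in H6). Lower in all 3 was miR-494-5p (-1.37 ± 0.52), and miR-379-5p was at 1307 ± 766 and 401 ± 144 (-1.71 ± 0.59). The predicted novel_mir889 was at least 2.48-fold higher (edgeR adjusted p = 0.240), and novel_mir656 at chr9:65630596-65630653 in an untranslated exon part of Rbpms2 at least 1.41-fold higher. The predicted novel_mir81 was at least 7.48-fold lower (4.65-fold without H1_1). DESeq2 called novel_mir81 (adjusted p = 0.00973), novel_mir889 (0.000775) and miR-328-3p (0.000474), whose counts are doubtful as at 6 h, and 2 miRNAs with the doubtful ones left out. The counts of miR-1981-3p (-5.21 ± 2.03, and -0.71 without H1_1) are doubtful likewise, with 623 H1 reads in the authors' deposited table and 152 in the sum of the libraries. Libraries did not overlap for 105 miRNAs (11.8%, chance at most 10%), and the median interval spanned a factor of 3.39. The mesenchymal miR-196a-1-3p was at 0.465 ± 0.194 in H1 and 3.11 ± 1.11 in H6, and miR-342-5p at 86.2 ± 38.0 and 37.7 ± 11.9. The predicted novel_mir687, at chr6:29348153-29348194 in an untranslated exon part of Calu, was at 0 in all H6 libraries, at least 8.67-fold lower (5.51-fold without H1_1).

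No list passed between 1 h and 6 h by camera, with the smallest adjusted p for the immediate-early list (0.0906, 11 of 12 members lower) and the miR-34 list (0.128, 7 of 7 lower). Among immediate-early members, miR-132-3p was at 41.8 ± 23.1 in H1 and 19.4 ± 7.28 in H6, and miR-212-5p at 84.2 ± 21.3 and 40.1 ± 32.4. The inflammation miRNA miR-146a-5p had a log2 fold change of -1.47 ± 0.57 (list adjusted p = 0.440). Other lists stood at 0.230 for germ cell (higher), 0.356 for let-7, 0.409 for mesenchymal and 0.451 for both the miR-23 and the Dlk1-Dio3 lists. Lists of miR-15, miR-322, smooth muscle, heat shock, Sfmbt2, epithelial, serum and RNA fragments had 0.696. Those of miR-17-92, miR-30, hypoxia and blood had 0.815, and miR-29 had 0.958. Apart from miR-503-5p, 0 members of any list passed adjusted over the list alone. Test and median differ in sign for miR-29 (test lower, median 0.23), hypoxia (test higher, median -0.11) and blood (test higher, median -0.01), and test and mean for heat shock (test lower, mean 0.53) and serum (test lower, mean 0.01). Further members had log2 fold changes of 1.35 ± 0.52 (miR-106b-5p), -0.86 ± 0.36 (miR-449a-5p), 0.71 ± 0.42 (miR-29b-2-5p), -0.70 ± 0.45 (miR-30b-3p), -1.5 ± 0.62 (miR-23b-5p), -1.52 ± 0.67 (miR-193a-5p), -0.74 ± 0.50 (miR-202-3p), 2.23 ± 1.11 (miR-451a) and 2.91 ± 1.45 (miR-126a-5p, SE throughout). Without H6_3 the last 2 were 0.26 and -0.68, and without H1_1 miR-132-3p, miR-193a-5p and miR-202-3p were at -0.53, -0.72 and -0.30. That of miR-106b-5p was 0.89 without H6_3, and those of miR-29b-2-5p and miR-30b-3p 0.44 and -0.43 without H6_2.

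Of 1576 piRNAs edgeR called 0 between both times (smallest adjusted p = 0.623), where 105 had an unadjusted p under 0.05 (62 higher, 43 lower; chance gives 78.8) and DESeq2 called 12. The abundant mmu_piR_000585 was at 12085 ± 1997 RPM in H1 and 6471 ± 730 in H6, with all 3 libraries lower. The LINE-1 piRNAs novel_pir1377 and novel_pir1373 were at 0 in all H6 libraries and at least 12.8-fold (4.38-fold without H1_1) and 5.38-fold lower than in H1. The predicted novel_pir3498, in an ERVL-MaLR repeat at chr2:27400951-27402008 that overlaps an exon, was at 219 ± 85.4 in H1 and 3300 ± 4033 in H6 (log2 3.91, and 2.27 without H6_2). Of 166 structural families edgeR called 0 (smallest adjusted p = 0.428), where 7 had an unadjusted p under 0.05 (4 higher, 3 lower; chance gives 8.3) and DESeq2 called 1. SNORA23 (RF00319) had 1, 10 and 0 reads in H1 and 6, 77 and 48 in H6. Libraries did not overlap for 105 piRNAs (6.66%, chance under 10% with ties at 0) and 13 structural families (7.83%, chance 10%), and median intervals spanned factors of 29.2 and 3.09. Log2 fold changes were 3.90 ± 1.43 for mmu_piR_000802, 2.83 ± 1.19 for mmu_piR_000159, 1.85 ± 0.96 for mmu_piR_036119, 1.69 ± 1.07 for mmu_piR_000958, -1.95 ± 1.41 for mmu_piR_032015, -1.06 ± 0.80 for mmu_piR_038351, -0.63 ± 0.64 for mmu_piR_018323 and -0.67 ± 0.68 for mmu_piR_002435. Without H6_2 mmu_piR_000802 was at 2.25, without H6_3 mmu_piR_000958 and mmu_piR_038351 were at 0.17 and -0.66, and without H1_3 mmu_piR_032015, mmu_piR_018323 and mmu_piR_002435 were at -0.65, -0.14 and -0.44. At 0 in all H1 libraries were novel_pir2482, at least 2.70-fold higher in H6, and mmu_piR_016536, at least 6.16-fold higher (1.73-fold without H6_2). Log2 fold changes of the families RF00009, RF00324, RF00271 and RF00428 were 1.76 ± 0.66, 1.29 ± 0.51, 1.95 ± 0.88 and 1.38 ± 0.63, and for RF01506, RF00005, RF02540, RF02467 and RF00405 -6.77 ± 1.77, -3.25 ± 1.20, -1.44 ± 0.61, -1.65 ± 0.78 and -1.10 ± 0.56. Without H1_3 those of RF01506 and RF00005 were -3.59 and -0.15, and without H1_1 those of RF02540 and RF00405 were -0.80 and -0.73.

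The responses at 1 h and 6 h were compared across RNAs, with the same 3 NC libraries in both. For miRNAs the log2 fold changes correlated with r = 0.519, beside 0.503 ± 0.0383 (SD) in 50 simulations without any change, and the covariance was 1.49 beside 1.05, a difference of 0.444. For piRNAs r was 0.627 beside 0.499 ± 0.0185, and the covariance 5.31 beside 3.28, a difference of 2.03. For structural families r was 0.287 beside 0.508 ± 0.0692, with a covariance difference of -0.20. Each RNA was drawn on its own in these simulations, so their SD leaves out RNAs that move together and is too small where they do. The distance from the simulated values therefore cannot be judged by this SD. The values of r depend on single libraries. For piRNAs r was 0.396 without H1_1 and 0.420 without a filter, both below the value simulated with all libraries, and for miRNAs it was 0.439 without H6_1 and 0.415 without a filter. For structural families it ran from 0.139 without H1_2 to 0.540 without NC_3, and was 0.581 without a filter. Shared calls numbered 0 in each class. At an unadjusted p under 0.05, 15 miRNAs, 36 piRNAs and 0 structural families went the same way at both times, beside means of 11.4, 30.5 and 1.9 in the simulations. Of these, 12 miRNAs were lower, where independent lists, which leave out the shared controls, give 1.25, and 35 piRNAs were higher, where they give 4.48. The 3 controls cannot be split, so part of any excess may come from the shared controls.

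Libraries differed strongly within groups. Across miRNAs, NC_1, NC_2 and NC_3 had mean correlations of 0.871, 0.889 and 0.860 with their own group. With the heated libraries these means were higher, at 0.891, 0.9045 and 0.889. Structural families gave the same order of means for each NC library, and piRNAs the opposite order. In all classes the best match of each NC library was a heated one, and that of NC_3 was H6_1. The plot of reads per library shows miRNAs of testis cells in NC_3, muscle miRNAs in H6_3 and miRNAs that were near 0 in some libraries of a group and abundant in others.

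**Figure D4:**
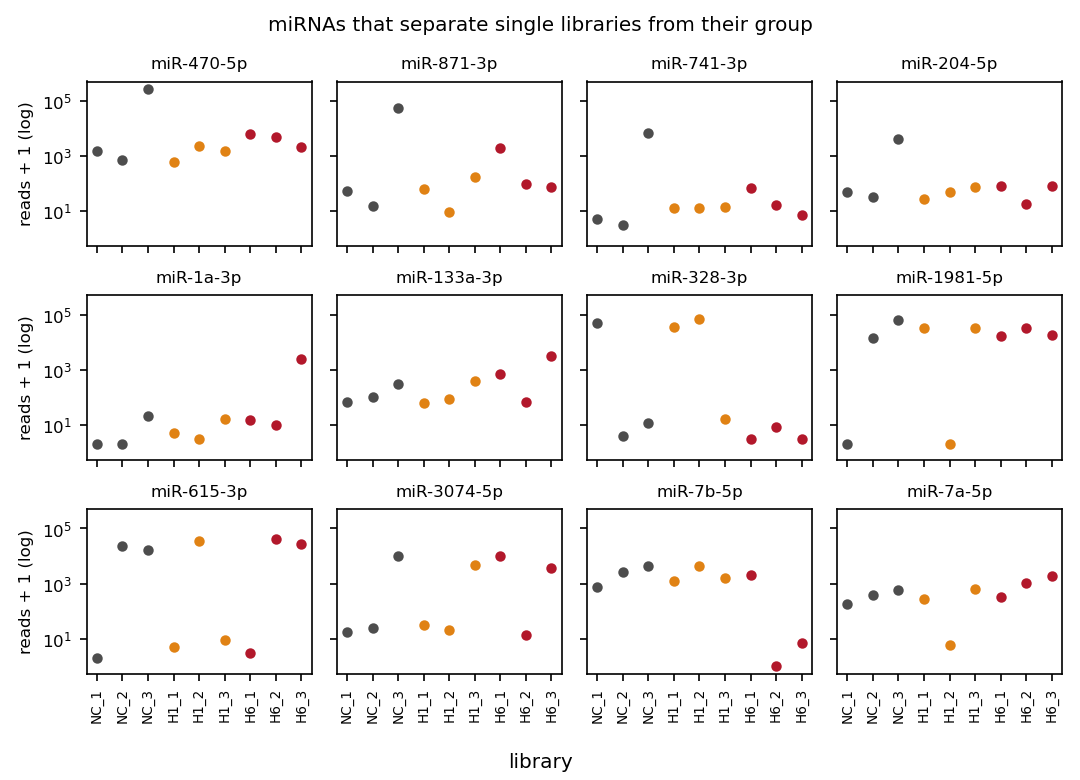
Reads plus 1 (y axis, log scale) of 12 miRNAs in the 9 libraries (x axis), coloured by group; each point is a library. In NC_3, miR-470-5p reaches 18091 RPM against 463 or less elsewhere, and the H6 values of miR-328-3p (2, 7 and 2 reads) are contradicted by the authors' pooled count of 289550.

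The authors' deposited tables, made from counts pooled over each group, list far more RNAs. The miRNA table lists 717 for H1 against NC (448 higher, 269 lower), 446 for H6 against NC and 683 for H6 against H1. All listed ratios in it are at least 1.00 on the log2 scale and all q-values at most 0.000997. Of the 213 listed at 1 h and tested here, 60 (28.2%) had an unadjusted edgeR p under 0.05 and 55 (25.8%) had all 3 libraries apart in the listed direction. At 6 h these were 39 (21.1%) and 21 (11.4%) of 185, and between both times 46 (21.4%) and 62 (28.8%) of 215. For piRNAs the authors' deposited table lists 1838 for H1 against NC, 2608 for H6 against NC and 2832 for H6 against H1, of which 674, 679 and 772 were tested here. An unadjusted p under 0.05 was found for 69 (10.2%), 159 (23.4%) and 105 (13.6%) of these, and 79 (11.7%), 89 (13.1%) and 88 (11.4%) had all 3 libraries apart in the listed direction. Of the RNAs listed and tested here, 0 passed the edgeR test, and most of those listed were not tested here. In the authors' deposited table miR-351-5p has a log2 ratio of -1.23 for H1 against NC, beside -1.25 from edgeR.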

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

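The tests of meiotic germ cells, of other testis cells, of RNA breakdown, of miRNAs that follow the groups, of the other arm of miR-3074, of the summed miR-7 reads, of the germ cell list without NC_3 with an estimated correlation and of missing miR-328-3p reads were chosen after the results were seen.

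Of 157 named RNAs and families, 8 had all 3 H1 libraries on one side of the NC mean and all 3 H6 libraries on the other. The difference between the times is the comparison of H6 with H1, and none of the 8 passed its edgeR test. All but let-7c-5p were named for a small p in that comparison, so the number 8 is not evidence by itself. The log2 fold change of H6 against H1 was 2.70 for miR-196a-1-3p, -0.38 for let-7c-5p, -0.86 for miR-449a-5p and -1.5 for miR-23b-5p, each with an edgeR adjusted p of 0.704. The predicted miRNA novel_mir687, in an exon of Calu, had a fitted value of -9.22 with H6 at 0 (at least 8.67-fold lower, adjusted p = 0.704). The LINE-1 piRNA novel_pir1377 had a fitted value of -9.93 with H6 at 0 (at least 12.8-fold lower, adjusted p = 0.623). For mmu_piR_036119 the value was 1.85 (adjusted p = 0.623) and for the family RF00324 it was 1.29 (adjusted p = 0.856).

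In NC_3, 18 named miRNAs stood over 4 times above every other library, among them miR-470-5p (39.1 times the highest other library), miR-741-3p (105), miR-871-3p (30.0) and miR-204-5p (35.4), against at most 3 such miRNAs in any other library. Depth is argued against, since 17 were still raised after thinning NC_3 to the shallowest library. A loss after heat is argued against as the source of these NC_3 levels. The other untreated libraries, NC_1 and NC_2, both lay above all 6 heated libraries for 1 of the 18, within the bound set before the test. The pick made the 18 low beside NC_3 in heated and untreated libraries alike, so it did not fix this count. A change of the germ cell list itself could not be decided. Without NC_3 it passed by camera toward higher levels at 6 h (adjusted p = 0.000531) but not at 1 h (0.385). With an estimated correlation it did not pass (adjusted p = 0.860 at 1 h and 0.879 at 6 h). Meiotic germ cells could not be decided, because the arms of miR-34b, miR-34c and miR-449a had a median log2 ratio of 0.66 in NC_3 and single arms differed. Of those with the lowest levels elsewhere, miR-34b-5p (7.76 RPM) had 1.97 and miR-449a-5p (10.6 RPM) had 0.10. Every arm was under the bound set for arguing against these cells, but levels of 503 for miR-34b-3p and 480 for miR-34c-3p elsewhere would hide a small share. Among named piRNAs, 7 stood over 4 times above every other library in NC_3, against at most 1 in any other library. Whether these piRNAs came from germ cells was not tested. Of the 18, 14 belong to the germ cell list (11) or the epithelial and Sertoli list (3), where 1.11 are expected from 41 of 664 (Fisher's exact test, one-sided p = 2.84e-15). The test takes miRNAs as independent, but the 18 include both arms of miR-743a and of miR-871 and come from 1 library, so this p overstates the evidence. RNA of other testis cells such as spermatogonia or Sertoli cells may be a source, though the Sertoli miRNA miR-202-3p was not raised there.

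In H6_2 and H6_3, 38 predicted piRNAs at 10 loci stood over 4 times above every other library, against at most 2 in any other of the 36 pairs of libraries. All 38 lie in long terminal repeats, which hold 53.1% of the predicted piRNAs tested. A heat response at 6 h could not be decided, because H6_1 lay above all NC and H1 libraries for 4 of the 38, but these were picked as low in H6_1, which also had the fewest piRNA reads (194338). More nuclear RNA could not be decided either, because H6_2 and H6_3 led in 14 of 117 snRNA and snoRNA families, where chance gives 3.25, while NC_1 and H6_2 led in 19, a bound set before the test that left out chance and shares H6_2. RNA breakdown could not be decided, because rRNA families took 11.4% in NC_1, where the median of these piRNAs was 0, beside 7.83% in H6_2 and 5.27% in H6_3. The NC_1 value met the outcome set for arguing against breakdown but rests on a single library, while H6_2 and H6_3 had the next highest shares.

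Among named miRNAs, 5 were near 0 in some libraries and abundant in others, and heat is argued against because 0 of the 5 followed the groups. For miR-328-3p the authors' deposited table holds 289550 reads in the H6 group where the libraries sum to 11, so reads missing from the table of libraries may be the cause, while the reads behind the RPM values exceed the listed reads in all groups (183159 in NC, 111597 in H1, 327357 in H6). For miR-7b-5p, with 0 and 6 reads in H6_2 and H6_3 and 746 to 4507 elsewhere, the sum with the near-identical miR-7a-5p had a largest gap between neighbouring libraries of only 1.31 times, so reads counted under either name may be the cause, with the caution that the counts of miR-7a-5p are doubtful too. For miR-3074-5p, the other arm miR-3074-2-3p had a log2 ratio of 0.56. This argues against loss of the whole transcript for the precursor that this arm is named for, and for no other. For miR-1981-5p, miR-3074-5p and miR-615-3p, reads counted under another name could not be decided, because 0 entries went the opposite way while the genomic entries hold up to 50.2% of the reads unnamed.

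In H6_3 alone the muscle miRNAs miR-1a-3p and miR-133a-3p and the endothelial miR-126a-5p stood at 237, 301.9 and 51.1 RPM, against at most 1.41, 46.1 and 7.05 elsewhere. The endothelial list as a whole, mostly the far more abundant arm miR-126a-3p, was not highest there, with 1042 RPM in H6_3 beside 1352 in NC_1 and 821 in H1_1.

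Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. RNAs past the threshold numbered 0 in the real split of every class and comparison, as many in all 10 splits, and at most 1 in another split (miRNAs, H1 and NC). In every class and comparison, a split mixing the groups gave more RNAs at an unadjusted p under 0.05 than the real split did. For piRNAs at 6 h the real split gave 159 and the highest other split 260, with as many in 4 of 10. For miRNAs the real split gave 61 at 1 h and 43 at 6 h, and the highest other split 108 and 129. Lists past the threshold numbered 3 at 1 h (highest other split 8, as many in 6 splits), 1 at 6 h (highest other 12, as many in 9) and 0 between both times (highest other 6, as many in 10), so some splits that mix the groups call several times more lists than the real one, which points to a structure among the libraries.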

How the results depend on the processing

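Robust estimation, quality weights, named miRNAs only, all named small RNAs in 1 fit, the loss of NC_3 and H6_3 together, the loss of miRNAs with doubtful counts, DESeq2 without an H6 library, the block with only NC and H1 and an estimated correlation without NC_3 were chosen after the data were seen. Counts of 0 by edgeR stayed at 0 under all other scalings, filters, thresholds and libraries left out, except without a filter and with DESeq2. DESeq2 called 4, 4 and 3 miRNAs (H1 against NC, H6 against NC, H6 against H1), 7, 79 and 12 piRNAs and 0, 0 and 1 structural families, and 4, 3 and 2 miRNAs with doubtful counts left out. For piRNAs at 6 h it called 143 without H6_1, 0 without H6_2 and 49 without H6_3, and 111, 0 and 40 on the piRNAs kept with all libraries. Without a filter edgeR called 34, 122 and 31 piRNAs and 5, 6 and 4 families. The cause was not tested.

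Lists past the threshold at 1 h numbered 3, all lower, and 0 with an estimated correlation. With a library left out they numbered 2 to 4, but none of the 3 passed without NC_3, where the 2 that did were higher, and 1 of 2 was higher without H1_1. With all named small RNAs in 1 fit, 1 was higher and 2 lower, and the Sfmbt2 list no longer passed. At 6 h they numbered 1, lower, and 0 with an estimated correlation or all named small RNAs in 1 fit, 2 with upper quartile scaling, 3 with at least 10 reads in 3 libraries, 4 without a filter (1 higher), 2 without NC_3 and H6_3 (both higher), and 1 to 5 with a library left out (the 1 without NC_3 higher, and 2 of 3 without H6_2). Between both times they numbered 0, and 2 with all named small RNAs in 1 fit, 1 with named miRNAs only, 2 without a filter, 1 without NC_3 and H6_3, and 0 to 3 with a library left out. The germ cell list turned to higher without NC_3 (adjusted p = 0.385 at 1 h, 0.000531 at 6 h, and 0.860 and 0.879 with an estimated correlation) and without NC_3 and H6_3 (0.416 and 6.55e-05), and the mesenchymal list at 6 h without both (0.0271). Signed by direction, with minus for lower, the adjusted p of the germ cell list ran with a library left out from -0.0544 (without H1_1) to 0.385 at 1 h and from -0.415 (without H6_3) to 0.000531 at 6 h. The correlation of both responses was 0.415, 0.420 and 0.581 for miRNAs, piRNAs and structural families without a filter, and with a library left out ran from 0.439 to 0.632, 0.396 to 0.612 and 0.139 to 0.540. Over 114 named RNAs, 2241 of 2309 values kept direction and side of the threshold, 51 passed it and 17 changed sign uncalled. Over 63 list results, 1120 of 1283 did, 40 passed, 20 no longer passed, 6 reversed and 97 changed sign uncalled.

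With the replicate block edgeR called 0 in every class and comparison, and the miR-322 list had an adjusted p of 0.00279 at 1 h and 0.00321 at 6 h. With the block and only the libraries of NC and H1, edgeR again called 0 in each class, and 1 list passed at 1 h, lower (miR-322, adjusted p = 0.0139), in a fit with fewer libraries. There 8 of 139 structural families had an unadjusted p under 0.05, against 9 without the block. Alternative pseudocounts do not apply to counts. At 194338 to 382447 piRNA reads per library, predicted piRNAs with under 10 reads are listed at 0, so lower levels were not detectable.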

Other observations

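The tests of predicted miRNAs in exons of heat-response genes were chosen after the values were seen, prompted by novel_mir81.

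Predicted miRNAs lay mostly in genes, with 480 of 822 in exons, 129 in introns, 83 antisense to a gene and 130 between genes. Among those in exons, 6 lie in genes of protein folding and the unfolded protein response. They are novel_mir81 in Dnajb9, novel_mir733 in Hsp90aa1 (chr12:110696214-110696299), novel_mir788 in Hspa1b (chr17:34958657-34958731), novel_mir243 in Serpinh1 (chr7:99346087-99346173), novel_mir675 in Hspe1 (chr1:55088348-55088402) and novel_mir25 in Stip1 (chr19:7022130-7022195). In Hspa1b, an inducible HSP70 gene, novel_mir788 had 11 reads in H1_1, 11 in H1_3 and 0 in the other libraries. In Serpinh1, which encodes a collagen chaperone, novel_mir243 had 14 reads in H1_1, 21 in H6_2 and 34 in H6_3.

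A hypothesis is that such entries are fragments of mRNAs induced by heat. They were detected 1 time in NC, 10 times in H1 and 4 times in H6, beside 294, 505 and 369 detections over all exonic entries. Their share per library was 1.00%, 0% and 0% in NC, 1.74%, 1.85% and 2.40% in H1 and 2.35%, 0.637% and 0.787% in H6. The exact permutation test over the 84 choices of 3 libraries gave a two-sided p of 0.0595. Without novel_mir81 the detections were 1, 7 and 4 and the p was 0.0952, so the hypothesis may hold but was not decided with these counts.

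The median level of the 38 piRNAs that stood out in H6_2 and H6_3 was 2281 RPM over piRNA reads in H6_2, 492 in H6_3, 75.3 in H1_1 and 48.7 in H1_2, and 0 in the other 5 libraries. The locus with the highest number of them, an ERVL-MaLR repeat at chr2:27400951-27402008, overlaps an exon.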
